A study of Mus musculus with 12 samples.

How the data were processed

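Expression was measured in mouse embryonic stem cells (mESC), OSKM iPSC, ESKM iPSC and mouse embryonic fibroblasts (MEF), with 3 single-colour Illumina bead arrays per group and 12 in all. Per the labels, total RNA was extracted with Trizol, treated with DNase I, cleaned on columns, and amplified to biotinylated cRNA. The pluripotent cells had grown for 4 days with LIF on gelatin. The sample labels give the same growth conditions for MEF, whereas the study description gives standard medium with 10% FBS, and the latter was followed here. The strain of mESC differs from that of the other groups, Cf1, so that strain cannot be separated from group in any comparison with mESC. No labels give a chip, date or batch.

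The deposited table used here holds log2 values, 1 per gene symbol for 9869 symbols, which range on the arrays from about 6 to 16. The unit was read from the values, whose range is that of log2 scanner signal. The quantiles of the 12 arrays are close to equal, so the authors had normalized the arrays to each other. The method, the background treatment, the way probes were combined and the selection of genes are not given in the sources used here. The table holds fewer genes than the 31509 symbols of the companion probe table, and 84.9% of its genes have a p under 0.05 in a one-way F test over the groups, so shares of genes called do not describe the whole transcriptome. The plan made before the data were examined was to start from the companion signals. Its 24 columns of signals and detection p-values were not used, because their headings match no sample label and many signals have lost their decimal mark. Only its gene symbols were used, to count the probes of each gene: 5778 genes have 1 probe on the array and 4090 several. The planned fallback, the deposited normalized values, was taken without further scaling or filter.

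Symbols were brought up to date with RefSeq names for the mouse assembly GRCm38.p6: 6010 were current, 3547 were former symbols of 1 gene, 53 of several genes, and 259 were not found. Of the former symbols 2942 were renamed, and 605 kept the name in the table because another entry bears the current symbol. Values near 6.5 lie near the lower end of the scale, so folds against such values are understated. The number of arrays limits the precision.

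All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit on group means and eBayes, 8 residual and 6.72 prior degrees of freedom), because 3 arrays estimate the spread of a gene poorly. Comparisons were ESKM iPSC, OSKM iPSC and mESC against MEF, ESKM against OSKM iPSC, and each iPSC group against mESC. P-values were adjusted by the Benjamini-Hochberg method per comparison over all 9869 genes, and a gene was called at an adjusted p under 0.05, with the number changed at least 2-fold given beside it. Where the text gives log2 differences the error is the SE of limma, and n is 3 arrays per group. Before the data were examined 26 gene lists were fixed, of which 25 had at least 3 measured members and were tested, and 353 of their 517 entries were measured. The list of genes of the 2-cell embryo was not tested for lack of measured members. Lefty1 and Lefty2 of the pluripotency list count as not measured, because the entries Leftb and Ebaf bear former symbols of both. Lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a comparison, with an estimated correlation beside it and with fry as an alternative. For some lists, such as germline genes (-0.0088), the estimate lay under the preset value. A call lost there was not lost to a higher correlation, so the settings differ in more than the correlation. Positions between mESC and MEF and similarities to mESC were compared between the iPSC groups by two-sided exact permutation tests on arrays. Overlaps of calls were set beside those of independent lists and of 100 simulations (seed 1) of unchanged groups that share their controls.

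Named genes follow a rule fixed before the data were examined. They are Pou5f1, Sox2, Klf4, Myc and Cdh1 in every comparison, the genes with the largest rises and falls among called genes whose groups of arrays do not overlap (8 and 8, or 4 and 4 for OSKM iPSC and mESC against MEF and OSKM iPSC against mESC), and per list the called members with the largest rises and falls, at most 2 each way. For a list with no called member it is the member with the largest difference. Which lists are described in which comparison was chosen after the values had been seen, and genes named outside the rule, in the weighing of patterns and among opposite calls, were chosen after their values were seen.

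The fit was tested on simulated data with 200 changed genes per comparison. A true change of 1 log2 unit was called in 97% to 98.5% of genes, one of 2 in 100% and one of 0.5 in 31.3% to 41.8%, with unchanged genes called in at most 0.124%. The simulated noise was independent and had the same spread in all groups, as the fit assumes. These rates therefore do not cover the wider spread of the OSKM iPSC arrays. Far more genes were called in the real comparisons than were changed here, which makes the adjusted threshold less strict there. Neither the shares of changed genes called nor that of unchanged genes carries over to those comparisons. Replicate numbers do not pair the arrays: over 18 pairs of arrays with the same number the correlation of residuals ran from -0.45 to 0.1, and 1 of 12 arrays was most like arrays of its own number. The alternatives tried were leaving out each array, fitting only the groups compared, array weights, an intensity trend with robust moderation, a larger offset, replicate number as a block, a 2-fold minimum, a minimum of 4 log2 units for positions, an estimated correlation and fry. Chosen after seeing the data were equal array medians, cyclic loess and quantile normalization on top of the deposited values, leaving out the dimmest genes, with a mean under 7.499 (7402 genes kept), and 1 entry per gene (9264 genes). A gene of the lists that rose in ESKM iPSC over mESC is not reported here, while the counts include it.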

Results

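Gene expression was measured on 12 single-colour Illumina bead arrays, 3 for each of 4 kinds of mouse cells. Mouse embryonic stem cells (mESC) are pluripotent cells derived from the early embryo. Mouse embryonic fibroblasts (MEF) came from E12.5 embryos and grew in medium with 10% fetal bovine serum. The labels give strain Cf1 for all groups except mESC, which are of another strain. The other groups were induced pluripotent stem cells (iPSC), which are made from differentiated cells by adding a few genes, and carried the labels OSKM and ESKM for the genes added. OSKM is the usual name for Oct4, Sox2, Klf4 and c-Myc. The labels do not spell out ESKM. From background knowledge of the study, it is the set in which E-cadherin takes the place of Oct4, and Cdh1, the E-cadherin gene, was therefore followed in every comparison together with Pou5f1 (Oct4), Sox2 and Klf4. Myc was on the same list but has no value in the table used. The table used holds log2 values of 9869 genes, and the number of arrays, 3 per group, limits the precision. Nothing in the labels says whether replicates were separate cultures or separate lines, so every p-value measures only the spread between these arrays, which may be technical.

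Fibroblasts stood far from the 3 pluripotent groups. Correlations across genes, which are not independent replicates, ran from 0.658 to 0.703 between MEF arrays and all others, against 0.951 to 0.984 between arrays of different pluripotent groups and at least 0.972 within any group. The first principal component held 84.0% of the variance. Array medians lay between 8.50 and 8.60 log2 units. OSKM iPSC arrays were the least alike, with a root mean square SD within the group of 0.262 log2 units against 0.175 in ESKM iPSC, 0.185 in mESC and 0.186 in MEF.

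ESKM iPSC were compared with MEF to ask which genes separate the reprogrammed cells from fibroblasts. Dppa5a, an RNA-binding protein gene of early embryos and pluripotent cells, rose 332-fold, from 7.01 ± 0.14 in MEF to 15.39 ± 0.11 in ESKM iPSC (mean ± SD of log2 values, n = 3 per group). The thyrotropin-releasing hormone gene Trh rose 297-fold, and the DNA methylation cofactor Dnmt3l 93.3-fold. The transcription factors Esrrb and Tfcp2l1 rose 92.4-fold and 90.6-fold, Esrrb by 6.53 ± 0.14 log2 units (± SE). In the other direction Bgn, which encodes the matrix proteoglycan biglycan, fell by 8.14 ± 0.13, Cav1, the caveolin gene, by 7.90 ± 0.12, and the growth factor gene Igf2 by 7.33 ± 0.13.

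Of the genes followed throughout, Pou5f1 rose by 5.77 ± 0.16 log2 units in ESKM iPSC over MEF, from 6.97 ± 0.06 to 12.74 ± 0.19, Cdh1 by 3.69 ± 0.14, Sox2 by 2.77 ± 0.16 and Klf4 by 0.88 ± 0.13. For Cdh1, Sox2 and Klf4 the array values do not show whether transcripts came from the added or the cells' own genes. If ESKM lacks Oct4, as background knowledge of the study has it, the Pou5f1 transcripts would have come from the cells' own gene. The phospholipase gene Pla2g1b rose by 6.38, the threonine dehydrogenase gene Tdh by 6.34 and Bex4 by 6.28 log2 units. Among the largest falls were the smooth muscle actin genes Acta2, which fell by 7.27, and Actg2, which fell by 6.96, the collagen cross-linking enzyme gene Lox, which fell by 7.19, and the protease inhibitor gene Timp2, which fell by 7.19. The largest fall of all, from 15.78 ± 0.17 to 6.78 ± 0.16, was that of 0610041G09Rik, a former symbol of Acta2, so that 1 gene has a pair of entries here. Actins share much of their sequence, and a probe may read more than 1 of them.

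By the lists of genes fixed in advance, all 35 measured genes of the pluripotency network rose in ESKM iPSC over MEF, with a median of 3.37 log2 units, and all 32 fibroblast genes fell, with a median of -3.94. Cell cycle genes rose in 23 of 26 cases, led by the replication licensing genes Cdt1 (2.86 ± 0.19) and Mcm2 (2.34 ± 0.13). Of 28 epithelial and adhesion genes 19 rose and 2 fell: the tight junction gene Cldn4 by 5.24 ± 0.18 and the protease inhibitor gene Spint1 by 4.39 ± 0.11 upward, and the keratin gene Krt19 and the P-cadherin gene Cdh3 fell by 0.82 and 0.65. Chromatin regulators rose in 17 of 20 cases, led by Dnmt3l and the Polycomb gene Cbx7 (4.48 ± 0.17), and Smarca2, an ATPase of chromatin remodelling complexes, fell by 2.26 ± 0.14. All 7 measured germline genes rose, among them Tdrd12 (4.36) and the homeobox gene Rhox5 (3.47). Of 18 antigen presentation and interferon genes 12 fell, with B2m, the light chain of MHC class I, at -3.76 ± 0.13 and H2-L at -2.70 ± 0.21, while 2 rose, Ifitm1 (0.93) and Irf1 (0.71). Of 13 growth arrest genes 9 fell, led by Igfbp3 (-4.15) and Ccnd2 (-3.97), and 2 rose, Trp53inp1 (0.83) and Gadd45a (0.47). Of 11 immediate-early and stress genes 8 fell, led by Jun (-2.22) and Fosb (-1.84), and 1 rose, Dusp1 (0.47). Of 11 genes of the primed epiblast, the later pluripotent state, 7 rose, led by the claudin gene Cldn6 (4.17 ± 0.18) and the DNA methyltransferase gene Dnmt3b (3.63 ± 0.25), and 3 fell, led by the activin inhibitor gene Fst (from 11.92 to 7.63) and by Sox4 (-1.71 ± 0.14), and this list was not called (adjusted p = 0.153). The call of Gadd45a was lost without ESKM iPSC replicate 2 (adjusted p = 0.0679) and without MEF replicate 3 (0.0542), and after cyclic loess those of Gadd45a (0.332) and Dusp1 (0.199) were lost.

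In this comparison limma called 7813 of 9869 genes at a Benjamini-Hochberg adjusted p under 0.05, 3972 higher and 3841 lower in ESKM iPSC, and 3728 of them changed at least 2-fold. All named genes had adjusted p of at most 0.0142. Adjusted over the list alone, the counts in the lists just described stayed as given, except that chromatin regulators rose in 18 cases. With camera's preset correlation 10 of 25 lists were called: those just described except the primed epiblast, with adjusted p from 1.1e-16 to 0.0311, and the reprogramming factors, of which all 4 measured rose (adjusted p = 0.00591). The pluripotency (0.00579), fibroblast (0.00579), germline (0.0465) and chromatin (0.0448) lists held their call with an estimated correlation. The calls of the others were lost: adjusted p = 0.0899 with an estimated correlation for the reprogramming factors and for the epithelial list, 0.137 for the cell cycle, 0.0955 for growth arrest and for immediate-early genes, and 0.434 for antigen presentation. The call of the immediate-early list was also lost without MEF replicate 3 (adjusted p = 0.0517), and those of the immediate-early and antigen presentation lists among the 7402 brightest genes (0.0781 each).

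**Figure D1:**
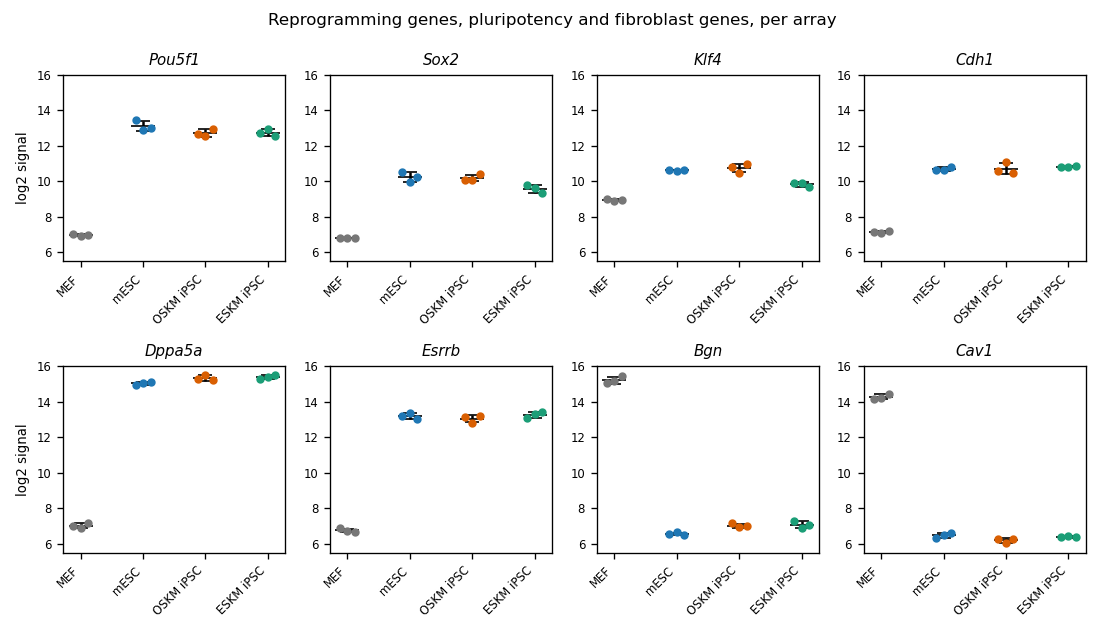
Log2 signal of 8 genes on each of the 12 arrays by group, with points for arrays and bars for the mean and SD of 3 arrays. Pou5f1, Dppa5a and Esrrb are near 7 in MEF and above 12 in the 3 pluripotent groups, and Bgn and Cav1 are above 14 in MEF and near 7 or below elsewhere.

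OSKM iPSC and mESC were set against MEF in the same way, as the standard reprogrammed cells and the pluripotent reference. Dppa5a again led the rises, by 8.32 ± 0.12 log2 units in OSKM iPSC and 8.03 ± 0.12 in mESC (n = 3 per group), followed by Trh with 7.79 and 7.49. Dnmt3l (6.58) and Tdh (6.45) came next in OSKM iPSC, and Esrrb (6.46) and Ooep, a gene of the egg cytoskeleton (6.40), in mESC. Bgn fell by 8.20 and 8.66 and Cav1 by 8.08 and 7.81 in OSKM iPSC and mESC, and H19, an imprinted non-coding RNA, fell by 8.62 ± 0.19 in OSKM iPSC. The entry 0610041G09Rik fell by 9.23 and 9.04, and Acta2 by 7.37 and 7.39. Pou5f1 rose by 5.74 in OSKM iPSC and 6.14 in mESC, Sox2 by 3.38 and 3.43, Klf4 by 1.80 and 1.68, and Cdh1 by 3.58 and 3.56.

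All 35 pluripotency genes rose and all 32 fibroblast genes fell in OSKM iPSC and in mESC alike, with Lox falling by 7.17 and 7.09. Glycolysis genes rose in 11 of 15 cases in OSKM iPSC and in 12 of 15 in mESC, with the glucose transporter gene Slc2a3 higher by 5.30 and 5.54, Hk2 higher by 1.86 in OSKM iPSC, the lactate dehydrogenase gene Ldhb higher by 2.15 in mESC, while Hk1 fell by 0.95 in OSKM iPSC. By limma 7782 genes were called between OSKM iPSC and MEF, 3966 higher and 3816 lower (3655 at least 2-fold), and 7497 between mESC and MEF, 3848 higher and 3649 lower (3458 at least 2-fold). Adjusted over the list alone, these list counts were the same. Camera called 10 and 12 lists. The pluripotency and fibroblast lists held with an estimated correlation in both comparisons, and the glycolysis list (adjusted p = 0.0199 and 9.4e-04) did not: adjusted p = 0.14 with an estimated correlation in OSKM iPSC and 0.058 in mESC. In OSKM iPSC its call also ended after cyclic loess (0.0848) and among the 7402 brightest genes (0.0504). The reprogramming factors and the epithelial, cell cycle, germline and chromatin lists were called upward in both comparisons and antigen presentation downward, and of these the germline and chromatin lists in mESC held (0.0448 each). Adjusted p with an estimated correlation was 0.0702, 0.091, 0.123, 0.0702, 0.0517 and 0.367 in this order in OSKM iPSC, and in mESC it was 0.0547 for the reprogramming factors and the epithelial list, 0.127 for the cell cycle and 0.43 for antigen presentation. The immediate-early list was called downward in OSKM iPSC (adjusted p = 0.0366), but not with an estimated correlation (0.12), after cyclic loess (0.0538), among the 7402 brightest genes (0.082) or without MEF replicate 3 (0.0553).

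Calls against MEF were mostly common to both iPSC groups: 3543 genes were higher in each and 3513 lower in each, where independent lists would share 1596 and 1485, and 17 were called in opposite directions. Simulated unchanged groups set against the same MEF arrays shared at most 1 call in 100 simulations, but such groups give hardly any calls, so this count does not measure how far shared arrays add to the overlap. The covariance of the log2 fold changes was 1.89 against 0.0123 simulated. With 3 MEF arrays the controls cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls. For the covariance, the simulated value is what noise in the shared arrays gives. The observed value lay 1.88 beyond it, which argues against such noise as the main source of the covariance.

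Along the axis from mESC (0) to MEF (1), over 1070 genes that differed at least by 2 log2 units between those groups, ESKM iPSC lay at -0.000968 ± 0.0022 and OSKM iPSC at -0.0107 ± 0.0037 (mean ± SD of array medians, n = 3). A value near 0 here does not mean a match to mESC gene by gene, since the sets of genes given below lay on opposite sides of 0. The difference between the iPSC groups had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow, so the design cannot reach 0.05. Over genes that differed at least by 4 log2 units the difference in position went from 0.00975 to 0.00328 (exact p = 0.3), so that the arrays of both groups no longer separated. For the 627 genes higher in MEF the values were -0.0258 ± 0.0039 and -0.0376 ± 0.004 (exact p = 0.1), and for the 443 genes higher in mESC 0.0673 ± 0.008 and 0.0574 ± 0.011 (exact p = 0.4). With the minimum of 4 these differences went from 0.0118 to 0.00201 (exact p = 0.4) and from 0.00983 to 0.00661 (0.5), with array medians set equal to 0.00738 (0.2) and 0.0173 (0.1), and after quantile scaling to 0.0138 (0.3) and 0.0116 (0.2). Across all genes the correlation with the mean of the mESC arrays was 0.962 ± 0.0011 in ESKM iPSC and 0.968 ± 0.007 in OSKM iPSC (exact p = 0.1). Without OSKM iPSC replicate 3 this difference went from -0.00645 to -0.00246, and that in position for the genes higher in mESC from 0.00983 to 0.00356. The median absolute difference from mESC was 0.300 ± 0.0077 and 0.279 ± 0.038 log2 units (exact p = 0.6), and without the same array the sign of that difference turned, from 0.0212 to -0.000569.

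ESKM iPSC were compared directly with OSKM iPSC to ask what the factor set changes. The entry Leftb rose by 2.94 ± 0.17 log2 units, from 9.29 ± 0.24 in OSKM to 12.23 ± 0.24 in ESKM iPSC (mean ± SD, n = 3 per group), and the entry Ebaf by 2.24 ± 0.19. Both names are former symbols shared by Lefty1 and Lefty2, near-identical genes for secreted inhibitors of Nodal signalling, and cannot be assigned to either. The interferon-induced membrane protein gene Ifitm3 rose by 2.84 ± 0.18, Xlr4a, a gene of an X-linked family of near-identical copies, by 2.67 ± 0.19, the glutathione peroxidase gene Gpx2 by 2.14 ± 0.13 and the matricellular protein gene Ccn2 by 1.86 ± 0.10. In the other direction Ndrg1, a gene induced by stress and low oxygen, fell by 1.92 ± 0.16, the growth factor gene Vegfa by 1.67 ± 0.20 and the transcriptional repressor gene Bhlhe40 by 1.54 ± 0.20.

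Pou5f1 and Cdh1 did not pass the test between the iPSC groups, with differences of 0.03 ± 0.16 (adjusted p = 0.93 by limma) and 0.11 ± 0.14 (0.705). Klf4 fell in ESKM iPSC by 0.91 ± 0.13 (adjusted p = 0.000542 by limma), from 10.75 ± 0.25 to 9.83 ± 0.13, and Sox2 by 0.61 ± 0.16 (0.0259). The call of Sox2 was lost without OSKM iPSC replicate 3 (adjusted p = 0.0781), without ESKM iPSC replicate 2 (0.0717) or replicate 3 (0.122), and when only these 2 groups were fitted (0.0703). Cabs1 rose by 2.36 and the secreted calcium-binding protein gene Smoc1 by 1.97. The other large falls were of Kdelr3, a receptor that returns proteins to the endoplasmic reticulum (-1.78 ± 0.22), 1700023M03Rik, a former symbol of Ikbip, which has an entry of its own (-1.43), the transcription factor gene Tcfl5 (-1.43), Fbxo2 (-1.37) and Rnf19a (-1.32).

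Among 7 measured germline genes 4 rose in ESKM over OSKM iPSC, led by Rhox5 (1.77 ± 0.11) and Rhox9 (1.59 ± 0.14), homeobox genes of a cluster on the X chromosome, and Taf7l fell by 0.49. Glycolysis genes fell in 3 of 15 cases and rose in 0, with Eno2 falling by 0.66 ± 0.15 and Slc2a3 by 0.56 ± 0.12. Of 35 pluripotency genes 5 rose and 5 fell, Dppa3 (1.22 ± 0.16) and Gdf3 (0.72 ± 0.15) the most upward and Klf4 and the Nodal co-receptor gene Tdgf1 (-0.82 ± 0.15) the most downward. Lefty1 and Lefty2 were also on this list as fixed in advance. The entries Leftb (2.94) and Ebaf (2.24), which rose more, cannot be assigned to either and were neither counted nor tested with it. Targets of beta-catenin, which binds the E-cadherin tail and also acts in Wnt signalling, rose in 3 of 11 cases, led by Sp5 (1.12 ± 0.16) and Notum (0.80 ± 0.15), and Cdx1 fell by 0.54. Of 28 epithelial and adhesion genes 3 rose, including Rab25 (0.86 ± 0.14) and the protease gene Prss8 (0.74 ± 0.15), and 0 fell. Of 18 antigen presentation and interferon genes 3 rose, Ifitm3 and Ifitm1 (1.00 ± 0.18) the most, and Tap2 fell by 0.44. Of 18 imprinted genes 3 rose, led by H19 (1.80 ± 0.19) and Mest (0.62), and Gnas fell by 0.66. Of 32 fibroblast genes 2 rose, Ccn2 and the matrix protein gene Sparc (0.52), and 2 fell, Tgfbi (-0.73) and Loxl1 (-0.49). H19, Ifitm3 and Ccn2 were also abundant in MEF, at 15.23, 14.81 and 13.72 log2 units. Without ESKM iPSC replicate 3 the calls of Loxl1 (adjusted p = 0.0574), Cdx1 (0.119), Taf7l (0.115), Eno2 (0.051), Sparc (0.116) and Tap2 (0.131) were lost, without replicate 2 those of Taf7l (0.125), Sparc (0.124), Mest (0.105) and Tap2 (0.1), and without replicate 1 those of Taf7l (0.082), Mest (0.0973) and Tap2 (0.0649). Without OSKM iPSC replicate 2 those of Cdx1 (0.0717), Taf7l (0.0961), Sparc (0.0961) and Tap2 (0.0598) were lost, and without OSKM iPSC replicate 3 those of Taf7l (0.0724), Mest (0.0654) and Tap2 (0.104). When only these 2 groups were fitted the calls of Cdx1 (0.0953), Eno2 (0.0553), Loxl1 (0.0656), Mest (0.0966), Sparc (0.0643), Taf7l (0.0584) and Tap2 (0.0929) were lost, and that of Tap2 also with a replicate block (0.0565) and a larger offset (0.0597), that of Taf7l with a replicate block, and that of Sparc with array weights (0.062) and with an intensity trend and robust moderation (0.0523).

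By limma 869 of 9869 genes were called between the iPSC groups, 470 higher and 399 lower in ESKM, of which 57 and 30 changed at least 2-fold. Adjusted over the list alone, glycolysis genes fell in 6 cases, pluripotency genes in 6 and fibroblast genes in 3, epithelial genes rose in 4 and fell in 1, antigen presentation genes rose in 5 and fell in 2, and the germline, beta-catenin and imprinted counts were the same. Camera called 2 of 25 lists, germline upward (adjusted p = 0.00547) and glycolysis downward (adjusted p = 0.00304), and neither held: adjusted p = 0.159 with an estimated correlation for both. For germline genes the estimate was -0.0088, under the preset value, so a higher correlation was not what ended that call. The pluripotency (0.536), beta-catenin (0.102), epithelial (0.579), antigen presentation (0.266), imprinted (0.266) and fibroblast (0.715) lists were not called, and the fibroblast list had a median of -0.03 beside a mean above 0. The number of genes called was 480 without ESKM iPSC replicate 2, 438 without ESKM iPSC replicate 3, and 396 when only these 2 groups were fitted.

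**Figure D2:**
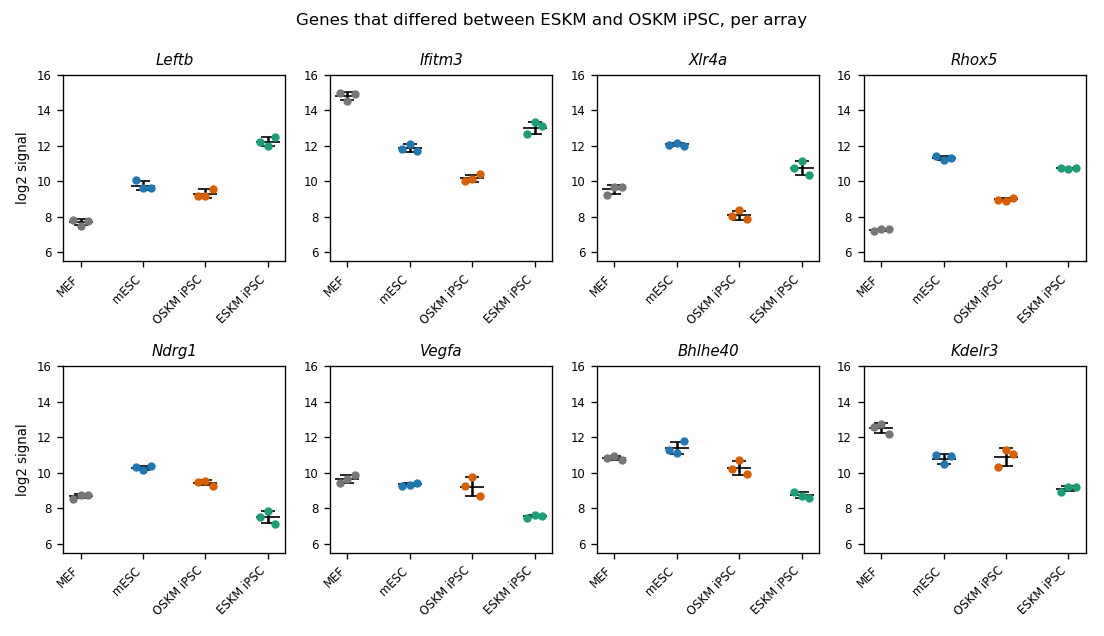
Log2 signal of 8 genes on each of the 12 arrays by group, with points for arrays and bars for the mean and SD of 3 arrays. The upper row holds genes higher in ESKM than in OSKM iPSC, such as Ifitm3 (13.02 against 10.18), and the lower row genes that were lower, such as Ndrg1 (7.51 against 9.43).

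ESKM iPSC were also compared with mESC, to ask how the reprogrammed cells differ from embryo-derived ones. Gpx2 rose by 2.67 ± 0.13 log2 units, from 9.28 ± 0.06 in mESC to 11.94 ± 0.19 in ESKM iPSC (mean ± SD, n = 3 per group), and Leftb by 2.48 ± 0.17. The falls were led by Ndrg1 (-2.78 ± 0.16) and Bhlhe40 (-2.65 ± 0.20), and the others named were Gm5091 (-2.33), Kctd19 (-2.28), Ddit3, a transcription factor gene of the unfolded protein response (-2.28 ± 0.18), Txnip, an inhibitor of glucose uptake (-2.22 ± 0.18), the immediate-early gene Fos (-2.20 ± 0.15) and Gadd45g (-2.06 ± 0.22). Klf4 fell by 0.79 ± 0.13 and Sox2 by 0.66 ± 0.16. Pou5f1 differed by -0.37 ± 0.16 (adjusted p = 0.0844 by limma) and Cdh1 by 0.13 ± 0.14 (0.506), and neither passed the test.

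Further rises over mESC were those of 2900078C09Rik (2.12), Enox1 (1.99), Cabs1 (1.96), 5830411I20 (1.94), the trypsin inhibitor gene Spink1 (1.94) and Ppp1r10 (1.77). The name 2900078C09Rik is a former symbol of Mras, whose own entry rose by 0.444, so the entries differ on the size of the rise. Immediate-early and stress genes fell in 8 of 11 cases, with a median of -0.59, and rose in 0. Glycolysis genes fell in 11 of 15 cases, with a median of -0.55, led by Hk1 (-1.25 ± 0.19) and Aldoa, an enzyme gene of the same pathway (12.9 ± 0.14 against 13.9 ± 0.10, mean ± SD). Primitive endoderm genes fell in 7 of 12 cases, led by the basement membrane collagens Col4a1 (-1.77 ± 0.14) and Col4a2 (-1.71 ± 0.19). Beta-catenin targets rose in 5 of 11 cases and fell in 0, led by Cdx2 (1.19 ± 0.16) and Sp5 (1.19 ± 0.16). Of 35 pluripotency genes 11 rose and 6 fell: Gdf3 (1.07) and L1td1 (1.05) were the largest rises, and Fgf4 (-1.22) and Tet1 (-1.05) the largest falls. The entries Leftb (2.48) and Ebaf (1.435), not counted among these genes, rose more. Targets of LIF signalling fell in 6 of 11 cases, with Socs3, a feedback inhibitor of that pathway, at -1.02 ± 0.19, and rose in 0. Of 18 imprinted genes 6 rose, led by Phlda2 (0.69) and Peg10 (0.64), and 4 fell, led by H19 (8.41 against 9.92) and Cdkn1c (-1.01). Of 32 fibroblast genes 8 fell, with the collagen cross-linking gene Loxl1 at -0.86 ± 0.11 and the protease gene Mmp2 at -0.74, and 1 rose, the transcription factor gene Twist1 (0.57 ± 0.17). Of 28 epithelial and adhesion genes 7 fell, led by the keratin genes Krt19 (-1.33 ± 0.22) and Krt18 (-0.96 ± 0.15), and 2 rose, led by Rab25 (0.49 ± 0.14). Without ESKM iPSC replicate 1 the calls of Tet1 (adjusted p = 0.0835), Mmp2 (0.151), Rab25 (0.0581) and Phlda2 (0.135) were lost, without replicate 2 that of Twist1 (0.0679), and without replicate 3 those of Tet1 (0.0625), Mmp2 (0.0977), Rab25 (0.0574) and Phlda2 (0.074). Without mESC replicate 1 those of Mmp2 (0.0659) and Phlda2 (0.0516) were lost, without mESC replicate 2 those of Twist1 (0.0597), Mmp2 (0.0679) and Phlda2 (0.0949), and without mESC replicate 3 those of Tet1 (0.109), Mmp2 (0.142) and Phlda2 (0.0517). A larger offset also ended that of Mmp2 (0.059).

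By limma 3424 genes were called between ESKM iPSC and mESC, 1558 higher and 1866 lower in ESKM iPSC, of which 130 and 229 changed at least 2-fold. Which direction held more genes depended on the scaling: 45.5% of those called were higher here, 48.1% after cyclic loess, 50.5% with array medians set equal and 51.8% after quantile scaling. Adjusted over the list alone, glycolysis genes fell in 12 cases, pluripotency genes rose in 13, imprinted genes rose in 7 and fibroblast genes fell in 7, and the other counts were the same. Camera called 4 lists: glycolysis (adjusted p = 2.7e-05), immediate-early genes (0.000283) and primitive endoderm (0.00217) downward, each at 0.0407 with an estimated correlation, and beta-catenin targets upward (0.0242), whose call was lost: adjusted p = 0.312 with an estimated correlation. The pluripotency (0.23), LIF target (0.194), imprinted (0.434), fibroblast (0.23) and epithelial (0.494) lists were not called. The strain differs between the groups and cannot be separated from reprogramming. The call of the beta-catenin list was also lost without mESC replicate 3 (adjusted p = 0.0521).

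OSKM iPSC were compared with mESC to ask the same of the standard reprogrammed cells. Xlr4a fell by 3.99 ± 0.19 log2 units, from 12.07 ± 0.08 in mESC to 8.08 ± 0.26 in OSKM iPSC (mean ± SD, n = 3 per group), and further falls were those of H19 (-3.31 ± 0.19), Rhox5 (-2.33 ± 0.11) and the fatty acid-binding protein gene Fabp3 (-2.29 ± 0.16). The largest rises were those of Enox1 (1.60 ± 0.22 log2 units), Nt5e, which encodes an enzyme that makes adenosine (1.59 ± 0.15), Serpinb6, a former symbol of Serpinb6a (2.83-fold), and Zdbf2 (2.82-fold). Serpinb6 rose from 6.48 in mESC, near the lower end of the scale, to 7.98 in OSKM iPSC. It is among the dim genes higher in both iPSC groups described below, for which a step shared by the iPSC arrays stays open. None of the genes followed throughout passed the test: Pou5f1 differed by -0.40 ± 0.16 (adjusted p = 0.0761 by limma), Sox2 by -0.05 ± 0.16 (0.847), Klf4 by 0.12 ± 0.13 (0.522) and Cdh1 by 0.02 ± 0.14 (0.934). Without OSKM iPSC replicate 3 Pou5f1 passed it (-0.52, adjusted p = 0.0377 by limma).

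Immediate-early and stress genes fell in 7 of 11 cases, with Fos at -1.98 ± 0.15 and Ddit3 at -1.69 ± 0.18. Primitive endoderm genes fell in 7 of 12 cases, led by Amn (-1.31 ± 0.22) and the endocytic adaptor gene Dab2 (-1.23 ± 0.11), germline genes in 4 of 7, led by Rhox5 and Tex19.1 (-0.81 ± 0.16), glycolysis genes in 6 of 15, led by Ldhb (-0.88 ± 0.14) and Hk1 (-0.70 ± 0.19), and endothelial genes in 5 of 7, led by Vwf (-0.87 ± 0.17) and Egfl7 (-0.71 ± 0.21). None of these 5 lists had a member that rose. Of 35 pluripotency genes 6 rose, led by L1td1 (1.05 ± 0.20) and Zfp296 (0.96 ± 0.18), and Fgf4 fell by 0.96 ± 0.24. Of 32 fibroblast genes 4 fell, led by Ccn2 (-1.61 ± 0.10) and Sparc (-1.02 ± 0.14), and 0 rose. Of 18 imprinted genes 3 fell, led by H19 and the cell cycle inhibitor gene Cdkn1c (-0.55 ± 0.19), and 3 rose, led by Peg10 (0.53 ± 0.12) and the non-coding RNA Kcnq1ot1 (0.48 ± 0.16). Without mESC replicate 1 the calls of Egfl7 (adjusted p = 0.121), Kcnq1ot1 (0.104) and Cdkn1c (0.163) were lost, without mESC replicate 2 that of Kcnq1ot1 (0.0671), and without mESC replicate 3 those of Egfl7 (0.079), Fgf4 (0.0546), Hk1 (0.0782), Kcnq1ot1 (0.114) and Cdkn1c (0.147). Without OSKM iPSC replicate 1 those of Egfl7 (0.0869), Kcnq1ot1 (0.154) and Cdkn1c (0.116) were lost, without OSKM iPSC replicate 2 that of Hk1 (0.0557), and without OSKM iPSC replicate 3 those of Kcnq1ot1 (0.108) and Cdkn1c (0.0828). When only these 2 groups were fitted the calls of Fgf4 (0.0523), Kcnq1ot1 (0.12), Cdkn1c (0.0782) and Egfl7 (0.0575) were lost, with a larger offset those of Kcnq1ot1 (0.0503) and Cdkn1c (0.0506), with array medians set equal that of Cdkn1c (0.0617) and with array weights that of Egfl7 (0.0539). By limma 2444 genes were called, 1047 higher and 1397 lower in OSKM iPSC, of which 49 and 108 changed at least 2-fold. Here too the larger direction depended on the scaling, with 42.8% of those called higher, 45.9% after cyclic loess, 51.7% with array medians set equal and 51.6% after quantile scaling.

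Adjusted over the list alone, 8 immediate-early genes fell, 8 pluripotency genes rose and 3 fell, and the other counts were the same. Camera called 6 lists in OSKM iPSC against mESC. Immediate-early genes (adjusted p = 5.1e-05) and primitive endoderm (0.000685) held their call, at 0.0269 and 0.0349 with an estimated correlation. The others lost it: adjusted p = 0.0703 with an estimated correlation for germline genes (0.00627 preset), 0.134 for glycolysis (0.00699 preset), 0.0879 for endothelial genes (0.0119 preset) and 0.469 for the upward pluripotency list (0.0322 preset), whose call also ended after cyclic loess (0.108), after quantile scaling (0.138), among the 7402 brightest genes (0.0559) and without mESC replicate 1 (0.0639) or OSKM iPSC replicate 1 (0.167) or replicate 3 (0.0863). The number of genes called was 1606 without mESC replicate 1, 1521 without mESC replicate 3 and 1508 when only these 2 groups were fitted. The fibroblast (0.144) and imprinted (0.975) lists were not called, and the imprinted list had a median of -0.04 and a mean of -0.14 beside an upward test.

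Against mESC, 756 genes were higher in both iPSC groups and 984 lower in both, where independent lists would share 165.3 and 264.1, and 31 were called in opposite directions. Simulated unchanged groups set against the same mESC arrays shared 0 calls in 100 simulations, which says as little as above about the shared arrays. The covariance of the log2 fold changes was 0.134 against 0.0122 simulated, and their correlation across genes 0.747 against 0.498. The mESC arrays cannot be split into parts of at least 2 either, so part of the excess in shared calls may come from the shared arrays. The observed covariance lay 0.122 beyond the simulated one, which argues against noise in these arrays as its main source. Both iPSC groups also differ from mESC in strain, which can give calls common to both and cannot be separated from reprogramming. The number of genes called in the same direction, 1740, came to 1139 without mESC replicate 1 and 1030 without mESC replicate 3.

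**Figure D3:**
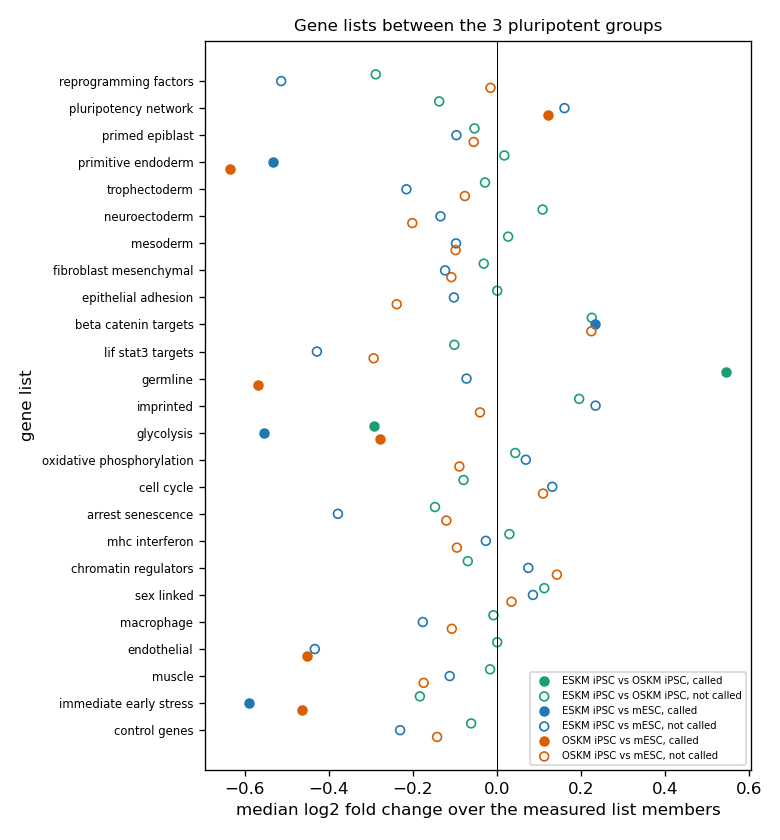
Median log2 fold change of each of 25 gene lists (rows) in the 3 comparisons between pluripotent groups, with filled points for lists called by camera at its preset correlation and open points for the others. Germline genes lie at 0.55 in ESKM against OSKM iPSC and at -0.57 in OSKM iPSC against mESC, and glycolysis genes lie below 0 in all 3 comparisons.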

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

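The tests of fibroblast RNA in this part were chosen after the result was seen, as were the genes given singly. Against mESC, 31 genes were called in opposite directions in ESKM and OSKM iPSC, 26 of them higher and 5 lower in ESKM iPSC, and so they differ between the iPSC groups by construction. The widest differences, in log2 units of ESKM minus OSKM iPSC, were those of Ifitm3 (2.84), Ebaf (2.24), Smoc1 (1.97), Serpinb6c (1.66) and Rhox9 (1.59), the only ones of at least 1.5. Ebaf, Serpinb6c and Rhox9 belong to families of near-identical genes, so the reading of their probes is uncertain.

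Ifitm3, Ccn2 and H19, which were abundant in MEF, were higher in ESKM than in OSKM iPSC. In this order they differed from mESC by 1.144, 0.248 and -1.505 log2 units in ESKM iPSC, and by -1.70, -1.61 and -3.308 in OSKM iPSC. Relative to mESC, a group of another strain, Ccn2 and H19 were thus low in OSKM iPSC rather than clearly raised in ESKM iPSC. RNA from remaining fibroblasts could raise Ifitm3, Ccn2 and H19 in ESKM iPSC. Ifitm3 would need 25.9% and Ccn2 7.97% of such RNA in ESKM iPSC, while over 135 genes at least 4 log2 units higher in MEF than in OSKM iPSC the 75th percentile of the implied share was 0.343%, which argues against that source for both. For H19 the implied share is 0.632%, which would raise the 14 genes at 13 or more in MEF and under 7.5 in OSKM iPSC by a median of 0.873 log2 units. Their observed median was 0.018 with an interquartile range of 0.203, which argues against it for H19 too. A difference between lines made with different factor sets stays open and was not tested, since the labels do not say how many lines were used.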

How the results depend on the processing

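The scalings on top of the deposited values, the filter on dim genes and the use of 1 entry per gene were chosen after seeing the data. With a 2-fold minimum the counts of genes called came to 3728 (ESKM iPSC against MEF), 3655 (OSKM iPSC against MEF), 3458 (mESC against MEF), 87 (ESKM against OSKM iPSC), 359 (ESKM iPSC against mESC) and 157 (OSKM iPSC against mESC), by construction. Fitting only the 2 groups compared gave 8082, 7500, 7743, 396, 4013 and 1508 genes in the same order, fewer than in the main run in each comparison that includes OSKM iPSC and more in the others. The arrays of OSKM iPSC spread more, with 0.262 log2 units against 0.175 to 0.186 in the other groups. The main fit used 1 spread per gene for all groups, which is then too small for OSKM iPSC. Main counts of comparisons with OSKM iPSC may therefore be too high. Array weights, an alternative that bears on this, were 0.41, 0.438 and 1.49 for OSKM iPSC replicates 1, 2 and 3. With them OSKM iPSC had 7793 genes called against MEF, more than in the main run. ESKM against OSKM iPSC had 746 and OSKM iPSC against mESC 2360, fewer than in the main run. A fit with a separate spread for each group was not run. Among the 7402 brightest genes OSKM iPSC against mESC had 1541 genes, ESKM against OSKM iPSC 4 lists, and the overlap against mESC 1053 genes. In the order given above, the lists called with an estimated correlation numbered 4, 2, 4, 0, 3 and 2, and with fry, which does not compare a list with other genes, 20, 20, 21, 5, 14 and 13. Leaving out 1 array gave 438 to 955 genes for ESKM against OSKM iPSC, 1521 to 2353 for OSKM iPSC against mESC, 1030 to 1665 in the overlap against mESC, and -0.000569 to 0.0336 for the difference in median distance from mESC. Replicate number as a block gave 7759, 7746, 7449, 712, 3282 and 2261 genes and 10, 11, 11, 2, 4 and 6 lists, and the numbers do not pair the arrays. Apart from that difference, whose sign turned without OSKM iPSC replicate 3, reversed signs were found only in genes that were not called: Pou5f1 in ESKM against OSKM iPSC with array weights (-0.063) and over left-out arrays (-0.065 to 0.153), Cdh1 there over left-out arrays (-0.011 to 0.288), Sox2 in OSKM iPSC against mESC with array weights (0.053) and over left-out arrays (-0.187 to 0.093), and Cdh1 there with array weights (-0.109), cyclic loess (-0.008), quantile normalization (-0.004) and over left-out arrays (-0.161 to 0.137). The cause of the reversals was not tested. Of 197 named gene results called, 29 lost the call under at least 1 alternative and none reversed, and of 44 list results called, 8 lost it under an alternative other than the estimated correlation. The excess of lower genes against mESC in both iPSC groups turned with array medians set equal and after quantile scaling. No added scaling moved the median difference of all genes by more than 0.074. Background correction, filters on detection p, other rules for probes and a chip block were planned and not run, since they need the companion signals or chip labels. Near 6.5 the signal limits what can be seen, and no detection p was used.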

Other observations

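The hypoxia and dim gene tests of this part were chosen after the result was seen, as were the splits of the arrays. Between the iPSC groups, further lists held single genes that moved. The early response gene Egr1 rose by 1.02 ± 0.22 log2 units in ESKM over OSKM iPSC and was the 1 of 11 immediate-early genes called. Evx1, a homeobox gene of the primitive streak, rose by 1.02 ± 0.13 as the 1 of 8 mesoderm genes called. Of 12 primitive endoderm genes Sparc rose and Col4a1 fell by 1.00 ± 0.14, of 11 primed epiblast genes Fst rose by 0.65 ± 0.12 and Otx2 fell by 0.98 ± 0.25, and of 13 growth arrest genes Ccnd1 rose by 0.50 ± 0.14 and Sesn1 fell by 0.64 ± 0.15. Respiratory chain genes rose in 2 of 24 cases, Ndufa5 (0.87 ± 0.22) and Ndufa2 (0.70 ± 0.16), endothelial genes in 2 of 7, Vwf (0.75) and Tek (0.68), and sex-linked genes in 2 of 8, Eif2s3y (0.71) and Tsix (0.50). Des fell by 0.86 as the 1 of 7 muscle genes called, Aurka by 0.53 as the 1 of 26 cell cycle genes, Kdm4c by 0.52 as the 1 of 20 chromatin regulators, and Klf4 was the 1 of 11 LIF targets called. No trophectoderm, neuroectoderm, macrophage or control gene was called: Eomes differed by -0.51, Sox11 by 0.33, Cd68 by 0.53 and Rpl13a by 0.46. With an intensity trend and robust moderation in limma, Eomes (adjusted p = 0.0397) and Cd68 (0.0485) passed. Adjusted over the list alone, 2 primed epiblast, 1 trophectoderm, 0 cell cycle, 2 growth arrest and 2 chromatin genes fell, 2 mesoderm, 1 LIF target, 4 respiratory chain and 1 macrophage gene rose, and 2 immediate-early genes rose and 2 fell, and the other counts of these lists were the same. None of these lists was called (adjusted p from 0.266 to 0.917), and the primitive endoderm list had a median of 0.02 beside a mean of -0.08 and a downward test, the macrophage list a median of -0.01 beside a mean of 0.07 and an upward test.

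Several of these calls between the iPSC groups were marginal and were lost under many alternatives. Fitting only these groups ended those of Otx2 (adjusted p = 0.113), Sparc (0.0643), Ndufa5 (0.0692), Ndufa2 (0.0648), Aurka (0.0652), Ccnd1 (0.0966), Kdm4c (0.0949) and Eif2s3y (0.0627). Aurka and Ccnd1 lost theirs under 8 of 16 alternatives, among them a replicate block (0.0587 and 0.0622) and an intensity trend with robust moderation (0.0616 for both), and array weights ended those of Ccnd1 (0.0785), Kdm4c (0.0665), Ndufa5 (0.0828) and Sparc (0.062). Folds shrank in some cases of a left-out array and grew in others: that of Ccnd1, 0.497 in the main run, was 0.378 without OSKM iPSC replicate 1 and 0.55 without ESKM iPSC replicate 1, and that of Otx2 -0.715 without OSKM iPSC replicate 1 and -1.036 without ESKM iPSC replicate 3, against -0.98. Without ESKM iPSC replicate 3 those of Otx2 (adjusted p = 0.0671), Sparc (0.116), Ndufa5 (0.0978), Ndufa2 (0.0684), Aurka (0.142), Ccnd1 (0.148), Kdm4c (0.0785) and Vwf (0.0836) were lost, and without replicate 2 those of Otx2 (0.0643), Sparc (0.124), Ndufa5 (0.119), Ndufa2 (0.0673), Aurka (0.0548), Ccnd1 (0.0866), Kdm4c (0.133) and Eif2s3y (0.07). Without ESKM iPSC replicate 1 those of Otx2 (0.0948), Aurka (0.138), Ccnd1 (0.0578) and Eif2s3y (0.0621) were lost, and Cd68 passed (0.0167). Without OSKM iPSC replicate 1 those of Otx2 (0.0827), Ndufa5 (0.0723), Aurka (0.0915), Ccnd1 (0.122) and Kdm4c (0.0832) were lost, without OSKM iPSC replicate 2 that of Sparc (0.0961), while Eomes passed (0.0218), and without OSKM iPSC replicate 3 those of Otx2 (0.0767), Aurka (0.0976) and Eif2s3y (0.0543), while Cd68 passed (0.0289). Against MEF, mESC also had the trophectoderm (adjusted p = 0.046) and LIF target (0.0276) lists called upward and the imprinted list (0.0276) downward, each lost with an estimated correlation (0.127, 0.0893 and 0.127), the trophectoderm list also with a replicate block (0.0505) and without OSKM iPSC replicate 2 (0.0518) or MEF replicate 2 (0.0511), and the LIF target list also among the 7402 brightest genes (0.0533).

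Genes known to respond to low oxygen were lower in ESKM than in OSKM iPSC, by a median of -0.46 log2 units over 29 measured genes of a list written after Ndrg1, Vegfa and Bhlhe40 had been seen to fall. Of these 12 fell and 0 rose, and 10 are also on the glycolysis list. Without those 3 genes, whose falls prompted the list, the median was -0.406 over 26 genes, of which 9 fell. Against mESC these 26 genes had a median of -0.71 in ESKM and -0.277 in OSKM iPSC (p = 0.00129 and 0.0425 with an estimated correlation), and all 29 genes -0.744 and -0.278 (0.00038 and 0.0188). Scaling between arrays would move genes of like level as well. The 555 genes outside the list, the 20 nearest in level to each of its genes, had a median of -0.009 with an interquartile range of 0.335. The list thus fell relative to genes of like level. This cannot decide on scaling, since the deposited arrays were already close to equal in their quantiles, which holds such a median near 0. A cause in 1 deviating array is argued against, as the median nearest 0 over left-out arrays was -0.382. Without the 3 genes the set test with an estimated correlation gave an unadjusted p = 0.000822. Leaving them out does not make the list independent of these data, so the p-values of this list only describe it. The glycolysis list fixed in advance had p = 0.159 with an estimated correlation, adjusted over all lists tested. That condition was added after this p was seen. A lower response as a whole may be a candidate explanation and stays open. Oxygen and cell density are not given by the labels and were not tested.

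Both iPSC groups stood at least 0.7 log2 units above mESC and MEF for 31 of 259 genes that lay under 7 in the latter. Among the other pairs of groups the highest count was 12 of 1325 such genes, for mESC and MEF. The highest share was 8 of 231, for mESC and ESKM iPSC. Of these 31, 1 was called between the iPSC groups. A step shared by the iPSC arrays, such as a batch, could give this count of 31 and cannot be told apart from reprogramming, since no batch is given. The limits of 7 and 0.7 were chosen after the data were seen, and the authors' unstated selection of genes bears on such counts.

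The 6 arrays of each comparison can be split in 10 ways, too few for a share under 0.05. Each other split mixes arrays of both groups, which puts a true difference into the spread and leaves part of it in the comparison. Counts from the other splits are therefore not those of groups without a difference. For counts of genes the real split gave 7813 (ESKM iPSC against MEF), 7782 (OSKM iPSC against MEF), 7497 (mESC against MEF), 869 (ESKM against OSKM iPSC), 3424 (ESKM iPSC against mESC) and 2444 (OSKM iPSC against mESC), and the highest other split 0, 0, 0, 0, 0 and 2, so that 1 of 10 splits, the real one, gave as many in each. For lists the real split gave 10, 10, 12, 2, 4 and 6, and the highest other split 9, 8, 9, 3, 3 and 5, with 1 of 10 splits giving as many in each except ESKM against OSKM iPSC, where 3 of 10 did.

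Of genes changed at least 2-fold against mESC in both iPSC groups, 32 were higher and 59 lower. The level in MEF was nearer to that of mESC for 21 of the higher and 27 of the lower genes, and nearer to that of the iPSC for 11 and 32.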
